A study of Mus musculus with 8 samples.

How the data were processed

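RNA of pooled 2-cell mouse embryos was measured on Affymetrix arrays, 8 arrays in 4 groups of 2 pools, with 100 embryos per pool. Per the labels, RNA was turned into biotinylated cDNA with a GeneChip WT Pico kit. The submitters' processing notes name Affymetrix Expression Console, without a version or a summarisation method. The deposited values are per transcript cluster on the log2 scale. The quartiles and maxima of the columns differ, so the columns do not share a distribution. In the first column (non-manipulated replicate 1) 1 cell holds a large whole number that no log2 level can be. The transcript cluster with that cell was left out and the rest of the column was used as log2.

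Of the 65956 transcript clusters deposited, 65955 were used. Gene symbols came from the array's annotation: 31257 clusters named 1 gene, 1492 several genes and 33206 none, and symbols of 2094 clusters were updated to current ones. Clusters that name several genes or none were left out of the gene tests. For the 442 genes on several clusters, the cluster with the highest mean over all arrays was used, which left 30700 genes. Chromosome positions and the genome build of the array design are not given in the sources used here and were not printed. No filter on low levels and no further normalization was applied to the main values.

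Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) in a single fit of 4 group means to all 8 arrays. This gave 4 residual and 6.83 total degrees of freedom per gene and a median standard error of 0.22 (0.31 for the interaction). P was adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. The 6 comparisons were the full treatment (Trim21 mRNA plus antibody) against Trim21 mRNA, antibody alone against non-manipulated embryos, Trim21 mRNA against non-manipulated embryos, the full treatment against antibody alone, the full treatment against non-manipulated embryos, and the interaction, which is the first difference minus the second. No day term can be fitted, since each group has its own day, and replicate numbers were not used as a block, since deviations of arrays with the same number did not correlate across genes (−0.191 to 0.143 between pairs of groups). Groups of 2 leave no exact test able to reach the threshold and no test of other splits or of outlying arrays.

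The comparisons, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined, except where an alternative is said to have been chosen after. The 25 lists were COP9 signalosome, cullin-RING and neddylation, 26S proteasome, transient 2-cell-stage transcripts, early lineage and pluripotency regulators, ribosome biogenesis, cytosolic ribosomal proteins, maternal oocyte transcripts, DNA replication, mitotic cell cycle, p53 targets, heat shock and chaperones, unfolded protein and integrated stress response, interferon and NF-kB response, NRF2 oxidative stress response, oxidative phosphorylation, mitochondrially encoded transcripts, splicing factors, RNA polymerase II and general transcription factors, mRNA decay machinery and glycolysis. Of other cell types there were markers of cumulus and granulosa cells, sperm, oviduct epithelium and blood and immune cells. The 24 lists with at least 5 measured genes were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. An estimated correlation, fry (which tests whether a list's genes move, on balance, one way) and ranks were alternatives. With an estimated correlation camera uses the 4 residual degrees of freedom, which leaves it little power whatever the correlation. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list only.

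Named genes were, per comparison, the 10 largest rises and the 10 largest falls among called genes whose pools of one group both lay above both of the other (5 and 5 for the full treatment against antibody alone and against non-manipulated embryos, with no such condition for the interaction). Cops3, Trim21 and all COP9 subunits were named too, and per list up to 4 called members with the smallest p, or the 2 with the smallest p where none was called. With fewer than 5 called genes the 5 smallest p were named. Predicted and clone symbols, small RNAs, immunoglobulin, T-cell receptor, olfactory, vomeronasal and clustered histone genes and pseudogenes (13541 genes) were counted but left out of the largest changes. Those that the text names beside them were named by another part of the rule or after their values were seen.

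Alternatives were quantile normalization, centring each array on its median, cyclic loess between arrays, a filter on low mean level, all transcript clusters, the mean of a gene's clusters, a trended robust prior and only the groups compared. Further alternatives were an added 2-fold threshold, the replicate number as a block, and each array left out in turn. Where a group then keeps 1 array, that array is assumed to vary like the other groups. Chosen after seeing the data were a spread for each group (limma array weights), leaving out genes at an array's ceiling, leaving out the antibody-alone group, list tests after quantile normalization and loess, the alternatives of the overlap between the antibody comparisons, and 10000 random lists matched on mean level in 20 bins. These random lists were drawn gene by gene, so their ranges leave out correlation between the genes of a list. The mean level used for matching includes the treated arrays. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

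The whole procedure was tested on simulated data with 30700 genes, 200 of them changed and the spread of each group as measured. At a 4-fold change 85.1% of changed genes were recovered for the full treatment against Trim21 mRNA, 86.6% for antibody alone against non-manipulated embryos and 53.7% for the interaction; at a 2-fold change 29.9%, 26.9% and 4.5% were. The unequal spread gave 0, 78 and 14 false calls, and 140 for the full treatment against antibody alone. With the 78 false calls came 18, 58 and 63 recovered genes at 2-fold, 4-fold and 8-fold. With the 140 came 31, 60 and 64, and with the 14 came 3, 36 and 56. In the simulated comparisons that involve the antibody-alone group, false calls were thus a larger share of called genes than the threshold allows. Where more genes change, as in the antibody comparisons, the adjustment of p is less strict, so the recovered shares do not carry over. The share of false calls in the data is not known.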

Results

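RNA levels were measured on 8 Affymetrix whole-transcript arrays, each with RNA from a pool of 100 mouse embryos (B6C3F1 x CD1 matings) at the late 2-cell stage. The pools formed 4 groups of 2: non-manipulated embryos, embryos injected at the pronuclear stage with mRNA for TRIM21, embryos injected with Trim21 mRNA together with an antibody against COPS3 (the full treatment), and embryos injected with the antibody alone. TRIM21 is a ubiquitin ligase that binds antibodies and directs them, with the protein they hold, to the proteasome. COPS3 is a subunit of the COP9 signalosome, which removes the ubiquitin-like protein NEDD8 from cullin ubiquitin ligases. The method acts on protein, so the level of Cops3 mRNA does not show whether COPS3 was removed. Embryos were cultured for 28 h per the protocol, while their age label gives 24 h in vitro, and per the labels cleavage to the 2-cell stage was normal without the antibody and stunted, with many zygotes undivided, in both groups that received it. Each group was treated on its own day of 1 week and both pools of a group came from the same day. Day and group therefore cannot be told apart, and every p of a single gene below measures spread between pools of a single day only. camera's p at the preset correlation compares a list's genes with all other genes, assuming a correlation of 0.01. It does not measure how far a list varies between pools. No p covers a difference between days. The number of arrays limits the precision.

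The distribution of levels differed between arrays. The median log2 level was 4.75 and 4.77 in non-manipulated embryos, 4.87 and 4.90 with Trim21 mRNA, 5.15 and 5.29 in the full treatment, and 5.24 and 4.86 with antibody alone. The standard deviation across transcript clusters was 2.71 on both non-manipulated arrays, against 2.38 and 2.27 in the full treatment. High levels stopped at a shared ceiling on 3 arrays, where 169 and 151 clusters (full treatment) and 136 clusters (antibody alone, replicate 1) held the array's highest value. The median change of all 30700 genes was 0.21 for the full treatment against Trim21 mRNA and 0.18 for antibody alone and 0.24 for the full treatment against non-manipulated embryos. Values after each array was centred on its own median, which removes this shift, stand beside the deposited scale. Across genes, which are not independent replicates, the pools of a group correlated at 0.9975 (non-manipulated), 0.9964 (Trim21 mRNA), 0.9857 (full treatment) and 0.9558 (antibody alone). The antibody-alone pools differed by more than 2-fold at 4616 genes, against 49, 97 and 809 genes between the pools of the other groups.

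Trim21 itself (transcript cluster TC0700003862.mm.1), which the injected mRNA should raise, stood at 9.77 and 10.14 with Trim21 mRNA and at 10.40 and 10.30 in the full treatment, against 6.27 and 5.65 in non-manipulated embryos and 6.76 and 6.37 with antibody alone. The arrays of the injected groups thus carried the transcript their labels name. All values below are differences of mean log2 level ± the standard error of limma's fit, with n = 2 pools per group.

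**Figure D1:**
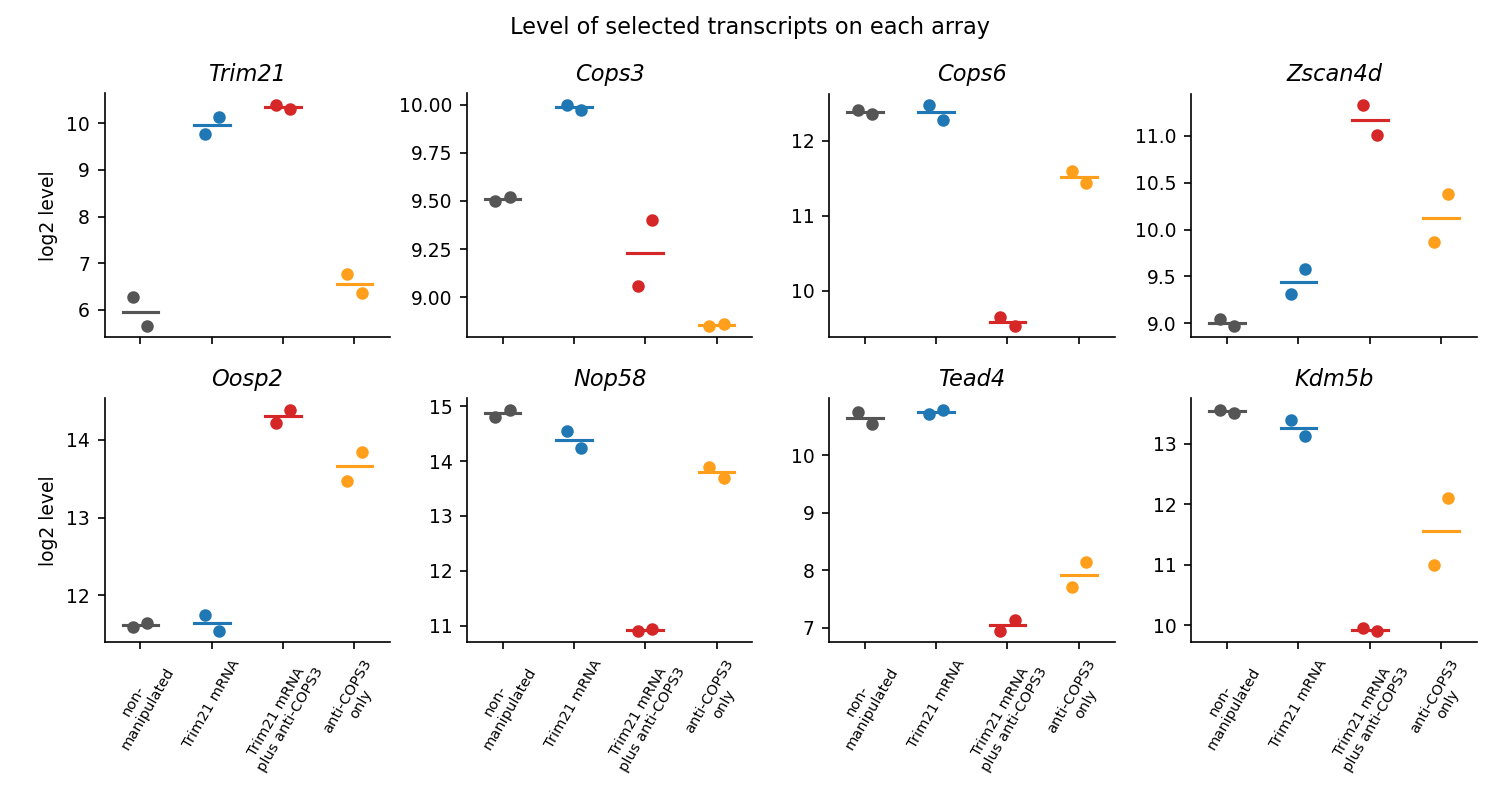
Log2 level (y axis, ranges differ between panels) of 8 genes on each array, by group (x axis); dots are single pools and lines are group means. Trim21 stood between 9.77 and 10.40 on the 4 arrays of groups injected with its mRNA and between 5.65 and 6.76 on the other 4; the difference of Cops3 between the full treatment and Trim21 mRNA was −0.75 as deposited and turned to 0.03 after quantile normalization.

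The full treatment against Trim21 mRNA asked what the antibody, given to remove COPS3, changed where both groups carried the injected mRNA. No group received a control antibody, so loss of COPS3 and effects of any injected antibody cannot be told apart in these comparisons. Genes that build ribosomes fell together: 50 of 51 measured ribosome biogenesis genes were lower (50 adjusted over the list alone), with a list median of −2.80. They included Bop1 (−3.51 ± 0.15), Nop14 (−3.39 ± 0.16) and Noc2l (−3.37 ± 0.16), which assemble the ribosomal subunits. All 33 measured cytosolic ribosomal protein genes fell (33 adjusted over the list alone, median −2.54), such as Rps7 (−3.19 ± 0.16) and Rpl38 (−3.17 ± 0.17). Of 31 genes of the 26S proteasome, which degrades ubiquitinated protein, 25 fell (28 adjusted over the list alone, median −2.15), with Psmd7 at −4.15 ± 0.21 and the ATPase Psmc5 at −3.92 ± 0.19. With camera's preset correlation the adjusted p of these lists was 9.9e-34, 1.2e-24 and 4.3e-19, and with an estimated correlation the adjusted p was 0.073, 0.11 and 0.073. After median centring the list medians were −3.01, −2.74 and −2.36, and after quantile normalization −1.98, −1.73 and −1.28. Only 33 of the 76 ribosomal protein genes could be measured, since 36 lay on clusters shared with other genes and the other 7 were not found under their symbol.

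Genes of RNA processing, transcription, cell division and energy supply fell as well. Of 50 splicing factors 38 fell (42 adjusted over the list alone, median −1.47), such as Hnrnpm (−3.03 ± 0.19). Of 43 genes of RNA polymerase II and the general transcription factors 25 fell and 1 rose (28 and 1 adjusted over the list alone, median −1.08), with the polymerase subunit Polr2d at −3.93 ± 0.19. Of 44 mitotic genes 31 fell and 1 rose (32 and 1 adjusted over the list alone, median −1.32), among them Cdc20 (−4.37 ± 0.16), an activator of the anaphase-promoting complex, and the kinase Cdk1 (−3.06 ± 0.17). Of 41 DNA replication genes 23 fell and 2 rose (27 and 2 adjusted over the list alone, median −0.96), with the replisome subunit Gins3 at −5.07 ± 0.18. Of 68 nuclear genes of oxidative phosphorylation 40 fell (47 fell and 1 rose adjusted over the list alone, median −1.17), such as the complex I subunit Ndufs8 (−3.54 ± 0.15). Of 30 heat shock and chaperone genes 17 fell and 1 rose (17 and 2 adjusted over the list alone, median −1.20), with the chaperonin subunit Cct3 at −2.80 ± 0.18. Each of these 6 lists passed camera's test with the preset correlation and had an adjusted p = 0.11 with an estimated correlation. All 6 medians stayed negative under every scaling but were smaller after quantile normalization, at −0.75 for splicing, −0.66 for RNA polymerase II, −0.58 for mitotic, −0.29 for replication, −0.68 for oxidative phosphorylation and −0.77 for heat shock genes. The change depended on level: all genes had a median of −0.60 at a mean log2 level of 8 to 10, −0.75 at 10 to 12 and −1.05 at 12 to 14. Beside 10000 random lists matched on size and level, the medians of heat shock, oxidative phosphorylation and splicing genes lay below the range of the middle 95% (−0.96 to 0.21, −0.67 to 0.03 and −1.23 to −0.07). Those of mitotic (−1.52 to −0.12), replication (−1.12 to 0.04) and RNA polymerase II genes (−1.28 to −0.02; −0.63 to 0.63 after quantile normalization) lay inside it as deposited. The ribosome biogenesis, ribosomal protein and proteasome medians lay below their ranges (−1.44 to −0.16, −1.41 to −0.02 and −1.62 to 0.00).

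Transcripts stored by the oocyte, most of which are cleared by the 2-cell stage, were higher: of 59 maternal genes 35 rose and 2 fell (39 and 4 adjusted over the list alone, median 0.93, adjusted p = 2.1e-08). They included the oocyte-secreted protein gene Oosp2 (2.66 ± 0.19), Nlrp9b (2.43 ± 0.20) and the apoptosis inhibitor Bcl2l10 (1.88 ± 0.17). In the Trim21 mRNA group itself the maternal median was −0.27 against non-manipulated embryos, and Bcl2l10 was lower too, without a call. Against non-manipulated embryos the maternal median of the full treatment was 0.61. Of 22 genes expressed transiently at the 2-cell stage, when the embryo's genome is switched on, 15 rose and 2 fell (17 and 3 adjusted over the list alone, median 1.77, adjusted p = 0.00076). Tcstv3 was at 1.81 ± 0.21 and the telomere regulator Zscan4d at 1.72 ± 0.22, while Sp110 fell (−2.14 ± 0.16). With an estimated correlation the adjusted p was 0.19 for the maternal and 0.25 for the 2-cell list. The medians were 0.72 and 1.56 after median centring and 1.88 and 2.55 after quantile normalization, and lay above the ranges of level-matched lists (−1.38 to −0.16 and −1.84 to 0.08). Of 23 early lineage and pluripotency regulators 9 fell and 1 rose (11 and 3 adjusted over the list alone, median −0.49, adjusted p = 0.24 with an estimated correlation). Among them were the trophectoderm regulator Tead4 (−3.72 ± 0.20), the histone demethylase gene Kdm5b (−3.34 ± 0.34) and the nuclear receptor Nr5a2 (−2.29 ± 0.30). The list's call ended after quantile normalization (median −0.10, adjusted p = 0.63) and loess (adjusted p = 0.53), and its median lay inside the level-matched range (−0.67 to 0.29).

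**Figure D2:**
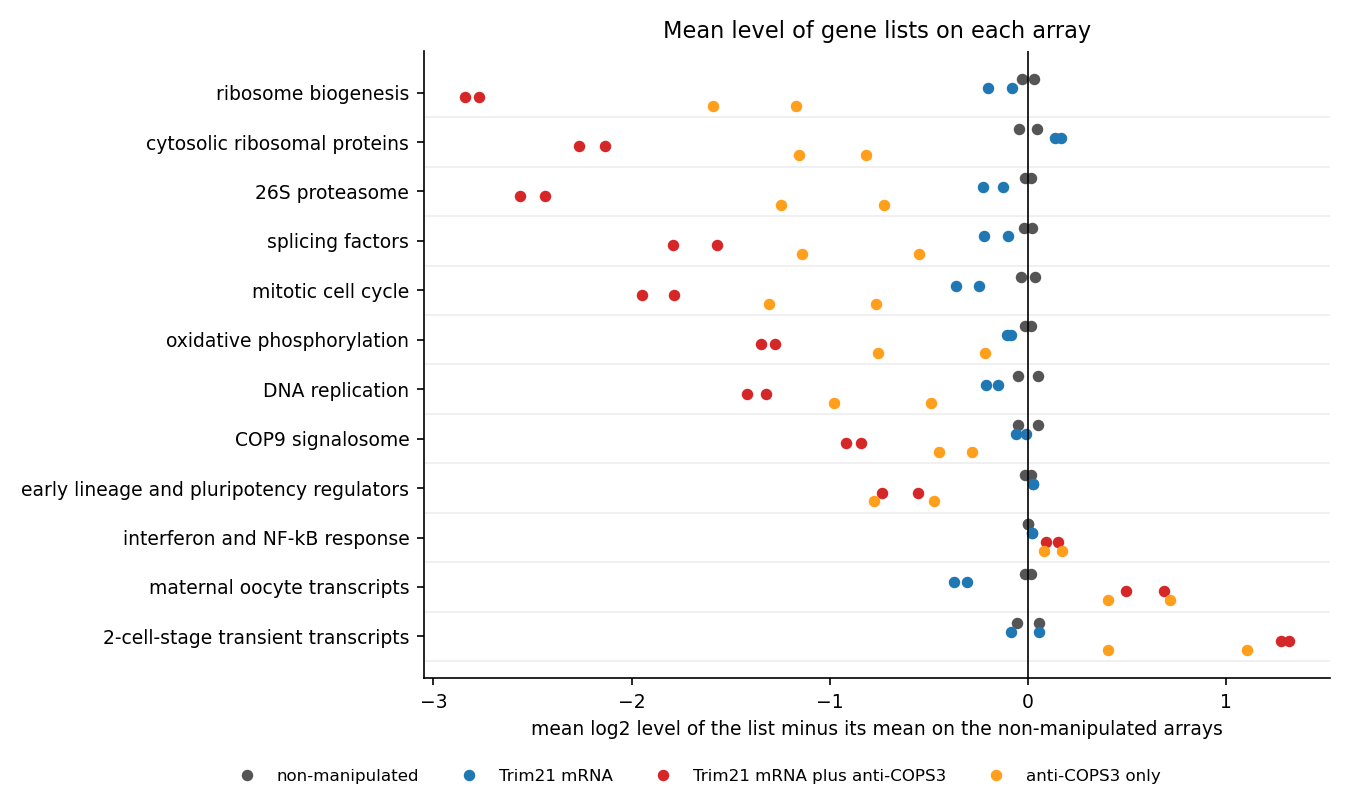
Mean log2 level of the measured genes of 12 lists (y axis) on each array, minus the mean of the non-manipulated arrays (x axis); dots are single pools, coloured by group. Ribosome biogenesis, ribosomal protein and proteasome genes lie lowest in the full treatment, with antibody alone between it and the other groups. Against non-manipulated embryos the median of the COP9 list turned from −0.71 to 0.31 after quantile normalization, that of the early lineage list from −0.45 to 0.02 and that of the interferon list from 0.33 to −0.07.

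Of the 10 subunits of the targeted complex, 3 had lower mRNA (3 adjusted over the list alone). The list median of −0.71 (adjusted p = 0.0019; adjusted p = 0.11 with an estimated correlation) turned to 0.14 after quantile normalization (adjusted p = 0.98) and 0.03 after loess (adjusted p = 0.95). Cops6 was lower, at −2.79 ± 0.16 (adjusted p = 8.3e-05), and stayed so under every scaling and without any 1 array. Cops4 was at −1.07 ± 0.17 (adjusted p = 0.0043), a call that ended after quantile normalization (−0.21, adjusted p = 0.35), after loess (−0.18, adjusted p = 0.45) and without Trim21 mRNA replicate 1 (adjusted p = 0.053). Cops3 mRNA was at −0.75 ± 0.16 (adjusted p = 0.017) as deposited, at −0.14 after loess (adjusted p = 0.69) and at 0.03 after quantile normalization (adjusted p = 0.93). Its call also ended without non-manipulated replicate 1 or 2 (adjusted p = 0.052 for both), Trim21 mRNA replicate 1 (0.12) or 2 (0.11), or full-treatment replicate 1 (0.063). The other 7 did not pass, from −1.54 ± 0.68 for Cops5, the catalytic subunit, to 0.15 ± 0.49 for Cops2. Among 33 cullin-RING and neddylation genes 16 fell and 2 rose (17 and 4 adjusted over the list alone, median −0.73, adjusted p = 0.11 with an estimated correlation). Nedd8 was at −2.99 ± 0.26 and Cul3 at −1.88 ± 0.18. The list's call ended after quantile normalization (median −0.38, adjusted p = 0.69) and loess (adjusted p = 0.79). The medians of this list and of COP9 lay inside their level-matched ranges (−1.14 to 0.11 and −2.11 to 0.38). Trim21 differed by 0.39 between these groups (adjusted p = 0.29; 1.25 after quantile normalization, adjusted p = 0.020).

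Stress and turnover lists held members of both directions. Of 23 NRF2 oxidative stress genes 9 fell and 3 rose (10 and 3 adjusted over the list alone, median −0.57), such as Taldo1 of the pentose phosphate pathway (−3.31 ± 0.18). Of 34 genes of the unfolded protein and integrated stress responses 12 fell and 2 rose (15 and 3 adjusted over the list alone, median −0.47), such as Phgdh of serine synthesis (−3.43, adjusted p = 0.0011). Of 31 p53 targets 10 fell and 2 rose (10 and 3 adjusted over the list alone, median −0.04), such as Sesn2 (−2.38 ± 0.20). Of 44 mRNA decay genes 16 fell and 4 rose (18 and 7 adjusted over the list alone, median −0.52), such as the exosome nuclease Exosc10 (−2.11 ± 0.14). All 4 lists passed as lower, with an adjusted p = 0.11, 0.17, 0.40 and 0.26 with an estimated correlation. Each call ended after quantile normalization (adjusted p = 0.11, 0.23, 0.48 and 1) and loess (0.20, 0.29, 0.46 and 0.96), where the direction of the test turned for mRNA decay, and the medians lay inside their level-matched ranges (−0.70 to 0.28, −0.68 to 0.23, −0.43 to 0.30 and −0.80 to 0.10). Without full-treatment replicate 2 the p53 list had an adjusted p of 0.094. Of 42 interferon and NF-kB genes 5 rose and 3 fell (5 and 3 adjusted over the list alone, median 0.30, −0.01 after loess, adjusted p = 0.097 by camera and 0.023 by fry), including Nfkb2 (1.21 ± 0.14) and Stat2 (−3.25 ± 0.38). The interferon median lay inside its level-matched range (0.17 to 0.40). Of 18 glycolysis genes 2 rose and 3 fell (2 and 4 adjusted over the list alone, median −0.17, adjusted p = 0.21, the test turning after loess, adjusted p = 0.96).

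Lists of other cell types that could reach a pool did not pass camera's test in this comparison, but fry, which takes each list alone, called oviduct (adjusted p = 0.028) and blood and immune markers (0.023). The median of 25 cumulus and granulosa markers was 0.22 (mean −0.03, and −0.10 after quantile normalization or loess; 1 higher and 1 lower). Medians were 0.38 for 17 sperm markers (2 higher and 2 lower), 0.28 for 16 oviduct markers (1 higher) and 0.38 for 13 blood and immune markers (2 higher; adjusted p = 0.076, and 0.036 without full-treatment replicate 1). Adjusted over the list alone the counts were 0 and 1, 2 and 2, 0, and 2. The medians of all these marker lists lay inside their level-matched ranges (0.07 to 0.43, 0.08 to 0.46, 0.13 to 0.48 and 0.10 to 0.50). After quantile normalization the sperm, oviduct and blood medians were 0.11, 0.01 and 0.08. All genes at a mean log2 level of 4 to 6 had a median of 0.31. Of 15 mitochondrially encoded transcripts 1 was measured, and that list was not tested.

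The largest falls of single genes included the zinc transporter gene Slc39a4 (−6.38 ± 0.70), the autophagy receptor gene Calcoco2 (−5.59 ± 0.32), Ssr2 of the translocon (−5.57 ± 0.27), Wdr74 of ribosome assembly (−5.54 ± 0.35) and the imprinted gene Phlda2 (−4.93 ± 0.20). The largest rises included the growth factor gene Tgfb2 (2.85 ± 0.14), Rela, an NF-kB subunit (2.82 ± 0.20), the DNA sensor gene Tlr9 (3.04 ± 0.27) and Kdelr2, a retrieval receptor of the secretory pathway (3.12 ± 0.43). These 9 genes stayed past the threshold under every scaling and without any 1 array, and of the 106 genes that the naming rule took and limma called, 94 to 106 kept their call, depending on which array was left out. In all 2677 genes rose and 4448 fell at an adjusted p under 0.05, of which 1285 and 3703 changed at least 2-fold. The share of changed genes that were higher was 37.6% as deposited, 20.9% after median centring, 48.5% after quantile normalization and 46.8% after loess. That share was 56.1% without the antibody-alone group and 52.1% with a spread for each group, where rises were the majority. The count of 7125 became 3366 and 3455 without Trim21 mRNA replicate 1 or 2, 4677 without full-treatment replicate 2 and 14192 without either antibody-alone array, and was 10891 with only these groups fitted and 11944 with a spread for each group.

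**Figure D3:**
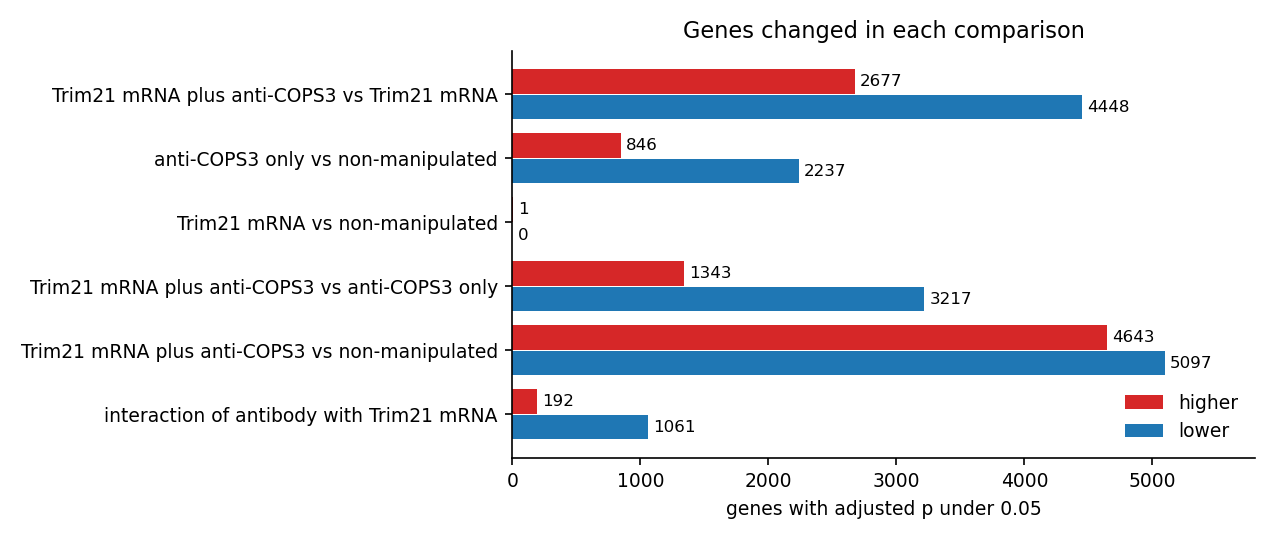
Number of genes (x axis) higher and lower at an adjusted p under 0.05 in each comparison (y axis), of 30700 tested; each bar is a count. Trim21 mRNA against non-manipulated embryos holds 1 gene, and the full treatment against non-manipulated embryos holds the most, 4643 higher and 5097 lower.

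Antibody alone against non-manipulated embryos asked what the antibody did without injected Trim21 mRNA; the injection itself differs between these groups too. Ribosome biogenesis genes were lower here as well, 29 of 51 (44 adjusted over the list alone, median −1.20), among them Bop1 (−2.07 ± 0.15), Nop2 (−2.59 ± 0.19), Mybbp1a (−3.42 ± 0.27) and Polr1a, the largest subunit of RNA polymerase I (−2.95 ± 0.20). Of 33 ribosomal protein genes 19 fell (28 adjusted over the list alone, median −0.99). Of 31 proteasome genes 12 fell (19 adjusted over the list alone, median −0.99), and of 50 splicing factors 17 (29 fell and 1 rose adjusted over the list alone, median −0.82). Of 44 mitotic genes 22 fell (27 fell and 1 rose adjusted over the list alone, median −0.86), with Cdc20 at −2.48 ± 0.16 and the kinase Plk1 at −2.94 ± 0.21. Of 41 replication genes 13 fell (20 fell and 2 rose adjusted over the list alone, median −0.58), with Gins3 at −2.86 ± 0.18. With an estimated correlation the adjusted p was 0.15 for ribosome biogenesis and the proteasome and 0.21 for the other 4 lists. The ribosome biogenesis median was −1.33 after median centring and −0.91 after quantile normalization, where the medians were −0.66 for ribosomal proteins, −0.67 for the proteasome, −0.53 for splicing, −0.52 for mitotic and −0.43 for replication genes. Of these 6 medians as deposited, that of replication genes lay inside its level-matched range (−0.65 to 0.05) and the others below theirs.

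Of 59 maternal genes 20 rose and 1 fell (31 and 3 adjusted over the list alone, median 0.72, adjusted p = 6.0e-05; adjusted p = 0.31 with an estimated correlation). Of 22 transient 2-cell genes 4 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.67, adjusted p = 0.0020; adjusted p = 0.31 with an estimated correlation). Both calls ended without antibody-alone replicate 2, at an adjusted p of 0.17 and 0.42. The medians were 0.58 and 0.54 after median centring and 0.94 and 0.98 after quantile normalization. Of 23 early lineage regulators 7 fell (9 fell and 1 rose adjusted over the list alone, median −0.28, adjusted p = 0.21 with an estimated correlation), and Tead4 was at −2.72 ± 0.20 (adjusted p = 0.0019). Of 10 COP9 subunits Cops6 passed, at −0.86 (adjusted p = 0.020), with 4 lower adjusted over the list alone (median −0.66, adjusted p = 0.21 with an estimated correlation). Its adjusted p was 0.12 after quantile normalization, 0.090 after loess, 0.18 and 0.15 without non-manipulated replicate 1 or 2 and 0.056 without either Trim21 mRNA array. Cops4 was at −0.66 (adjusted p = 0.054; 0.046 after median centring) and Cops3 at −0.65 (adjusted p = 0.053; 0.023 after median centring, 0.044 without either full-treatment array and 0.024 without antibody-alone replicate 2). Among single genes Ifitm3, an interferon-induced membrane protein gene, rose by 2.50 ± 0.20 (adjusted p = 0.0021) and Pramel16 by 2.50 ± 0.22 (adjusted p = 0.0029).

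The maternal and 2-cell medians lay above their level-matched ranges (−0.63 to −0.02 and −0.86 to 0.09) and the early lineage and COP9 medians inside theirs (−0.47 to 0.21 and −1.09 to 0.30). In all 846 genes rose and 2237 fell, and 27.4% of the changed genes were higher as deposited, 18.3% after median centring, 45.0% after quantile normalization and 44.2% after loess. Without antibody-alone replicate 2 more genes were called higher than lower. The median change of all genes was then 0.25, against 0.07 without replicate 1. camera called 17 of 24 lists, 15 lower and 2 higher, and fry also cumulus markers (median 0.22, adjusted p = 0.048, and 0.28 by camera). The cumulus median lay inside its level-matched range (0.06 to 0.36). With an estimated correlation 0 lists passed, and the adjusted p of the called lists was 0.15 to 0.37. The calls of COP9, cullin-RING, p53, heat shock, stress response, mRNA decay and oxidative phosphorylation genes ended under quantile normalization or loess. Without antibody-alone replicate 1 the calls of COP9 (adjusted p = 0.072), cullin-RING (0.13), stress response (0.13), mRNA decay (0.066) and p53 (0.29) genes ended too. The count of 3083 was 0 with only these groups fitted by limma, and 1177 with a spread for each group; 8509 genes had an unadjusted p under 0.05 in the fit of all 8 arrays. It was 94 and 156 without non-manipulated replicate 1 or 2, 1360 without a Trim21 mRNA array, and 5324 and 13792 without antibody-alone replicate 1 or 2. Of the 20 genes with the largest changes, 3 kept their call without non-manipulated replicate 1 (Ifitm3, Pramel16 and AY036118). Of all 93 genes that the naming rule took and limma called, list members included, 82 lost their call without non-manipulated replicate 1, 79 without replicate 2, 15 without either Trim21 mRNA array and 93 with only these groups fitted. The list members given above are those that kept theirs without any 1 array, apart from Cops6; Psmd7, Rps15, Mcm5, Kdm5b, Nr5a2 and Oosp2 were among those that lost it without either non-manipulated array.

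Trim21 mRNA against non-manipulated embryos is the injection control. Trim21 was the only gene called by limma, higher by 3.99 ± 0.26 (adjusted p = 0.048), and 1928 genes had an unadjusted p under 0.05. Its difference was 3.95 after median centring (adjusted p = 0.065), 3.76 after quantile normalization (0.18) and 4.12 after loess (0.11). The call also ended without either non-manipulated array (0.19 and 0.46), either Trim21 mRNA array (0.56 and 0.95) or either full-treatment array (0.49). Cops3 was at 0.47 (adjusted p = 0.68). Among the genes with the smallest p, none past the threshold, were Bcl2l10 (−1.41 ± 0.17) and Traj55 (1.36 ± 0.17), and Tcl1 was at −1.35 (adjusted p = 0.44). No member of any list was called over all genes; adjusted over the list alone 13 of 59 maternal genes and 2 of 31 p53 targets were lower, and 1 gene each of the mRNA decay and early lineage lists.

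Small shifts of whole lists were called with the preset correlation: 14 lists were lower, with medians from −0.34 (mitotic genes) to −0.13 (heat shock), maternal genes among them at −0.27, and ribosomal protein genes were higher by 0.11. Their adjusted p was 0.32 to 0.59 with an estimated correlation, and fry, which takes each list alone, called 0. After quantile normalization 7 lists were called and after loess 9. The ribosomal protein call ended after median centring (adjusted p = 0.057) and without Trim21 mRNA replicate 1 (0.057) or non-manipulated replicate 2 (0.17). Calls of splicing factors (adjusted p = 0.066) and ribosome biogenesis (0.082) ended without Trim21 mRNA replicate 2, and that of DNA replication (0.071) without non-manipulated replicate 1. Oxidative phosphorylation was called without that array (0.049) or either antibody-alone array (0.010), and cumulus markers without that array (0.0017). COP9 subunits had a median of −0.07 (0.04 after quantile normalization), and oviduct markers a median of 0.05 (−0.06 after quantile normalization) and a mean of −0.02; neither list passed. The gene count was 0 under the 3 scalings, and 2520 with only these groups fitted or 3739 with a spread for each group, since these pools varied least.

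**Figure D4:**
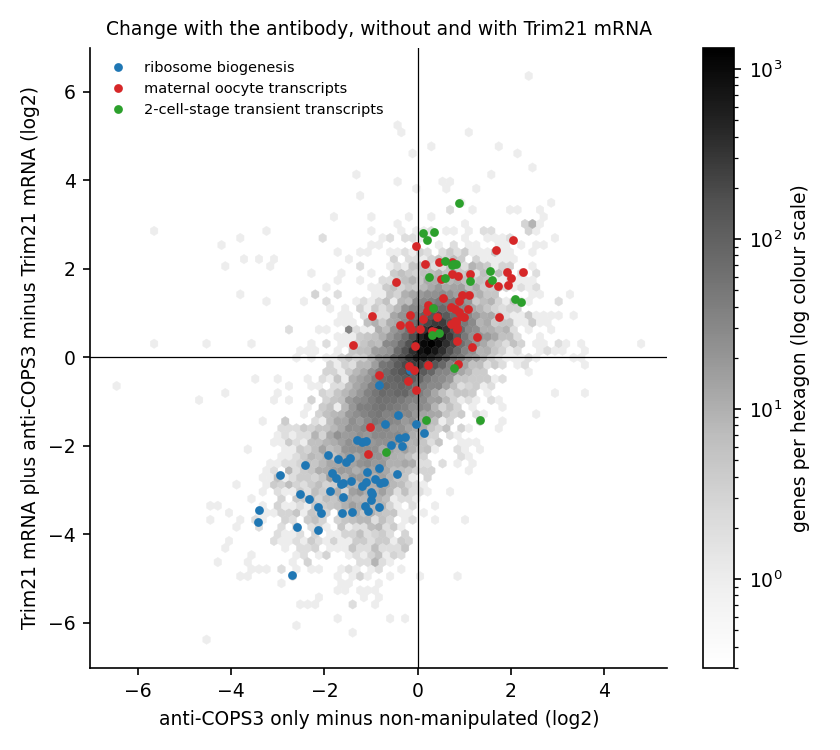
Log2 change of 30700 genes with antibody alone against non-manipulated embryos (x axis) and with the full treatment against Trim21 mRNA (y axis). Hexagons are shaded by the number of genes on a log scale, and coloured dots are ribosome biogenesis, maternal and transient 2-cell genes. Ribosome biogenesis genes lie in the lower left, with medians of −1.20 and −2.80.

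The antibody's changes with and without Trim21 mRNA share no array and could be set side by side. Across genes they correlated at 0.684 (Pearson) and 0.615 (Spearman). Of the genes that were lower with antibody alone, 1917 (85.7%) were also lower in the full treatment against Trim21 mRNA, where 324.1 would be shared if the calls were independent. Of those that were higher with antibody alone 389 (46.0%) were also higher there, where 73.8 would be shared, and 49 were called in opposite directions. These counts moved with the calls of antibody alone: lower in both were 69 genes (86.2%) and 120 (89.6%) without non-manipulated replicate 1 or 2, 860 (81.4%) and 861 (81.5%) without Trim21 mRNA replicate 1 or 2, and 3943 (71.6%) without antibody-alone replicate 2. Higher in both were 11 (78.6%), 17 (77.3%), 124 (40.9%), 118 (38.9%) and 3795 (45.8%) in that order, and 1247 (55.4%) without antibody-alone replicate 1. After quantile normalization 1099 (80.7%) were lower and 826 (74.0%) higher in both, and with only the groups compared in each fit 0 were, since antibody alone then had no calls. These numbers describe genes, which are not independent replicates, and groups that differ by day. The calls of both comparisons rest on a variance per gene estimated over all 8 arrays, so they are linked. The numbers given for independent calls are therefore no test of the overlap. Both changes also depended on level. Genes at a mean log2 level of 12 to 14 had medians of −1.05 with Trim21 mRNA and −0.39 without it.

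The difference between those changes was tested as an interaction. Ribosome biogenesis genes fell further with Trim21 mRNA present, by a median of −1.42 (18 of 51 lower, 33 adjusted over the list alone). So did ribosomal protein genes (−1.51; 16 of 33, 22 adjusted over the list alone) and proteasome genes (−1.10; 12 of 31, 16 adjusted over the list alone). Nop14 (−2.56 ± 0.22), Psmc5 (−3.20 ± 0.27), Psma3 (−2.93 ± 0.23), Ndufs8 (−3.12 ± 0.22) and Polr2d (−3.06 ± 0.27) kept their calls without any 1 array. Maternal genes rose further (median 0.29, 7 higher and 0 lower; 11 and 1 adjusted over the list alone), a call that ended without antibody-alone replicate 1 (adjusted p = 0.11). With an estimated correlation the adjusted p was 0.15, 0.17, 0.15 and 0.41 for these 4 lists, and the medians after quantile normalization were −0.92, −1.05, −0.70 and 0.81. Among single genes Phlda2 (−5.71 ± 0.29), Tsn (−4.36 ± 0.36), the pluripotency marker Dppa5a (−3.95 ± 0.23), Dcaf13, a cullin adaptor gene (−4.10 ± 0.33), Pdhb of pyruvate oxidation (−3.77 ± 0.30) and Trem1 (3.37 ± 0.32) kept their calls without any 1 array. Cops6 was at −1.92 ± 0.22 (adjusted p = 0.0076), a call lost without either non-manipulated array (0.068 and 0.074) or either Trim21 mRNA array (0.067 and 0.053). Most named genes lost theirs in this way: of 79 that the rule took and limma called, 65 and 67 did without non-manipulated replicate 1 or 2, 56 and 53 without Trim21 mRNA replicate 1 or 2, 17 and 31 without full-treatment replicate 1 or 2, and 0 without either antibody-alone array. Nop58, Rpl4, Rpl7, Rps7, Psmd7, Psmd12 and Cdk1 were among those lost without either non-manipulated array.

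In all 192 genes were higher and 1061 lower by this test, and 15.3% were higher as deposited, 11.6% after median centring, 45.4% after quantile normalization and 45.6% after loess. Of 24 lists 14 were called, with an adjusted p of 0.15 to 0.56 with an estimated correlation. Calls of cullin-RING, DNA replication, mitotic, stress response and RNA polymerase II genes ended after quantile normalization and loess. Several calls turned on 1 array. Without antibody-alone replicate 2 those of mitotic (adjusted p = 0.40), replication (0.84), RNA polymerase II (0.79), splicing (0.061), oxidative phosphorylation (0.053), NRF2 (0.15), cullin-RING (0.70) and stress response (0.63) genes ended. That of 2-cell genes (median 0.69) ended without antibody-alone replicate 1 (0.20), either full-treatment array (0.22 and 0.060), Trim21 mRNA replicate 1 (0.068) or non-manipulated replicate 1 (0.085). The cullin-RING and stress response calls ended too without full-treatment replicate 2 (0.26 and 0.29) or Trim21 mRNA replicate 1 (0.076 and 0.068), and the former without non-manipulated replicate 2 (0.054). Calls of p53 (0.019) and COP9 (0.043) genes appeared without antibody-alone replicate 1. The count of 1253 was 113 and 99 without non-manipulated replicate 1 or 2, 203 and 199 without Trim21 mRNA replicate 1 or 2, 579 without full-treatment replicate 2, and 4065 and 5663 without antibody-alone replicate 1 or 2. For early lineage genes the median (−0.14; 0.18 after quantile normalization) and mean (−0.04) were negative where the test pointed up. For interferon and cumulus genes the median (0.09 and 0.02) and mean (−0.02 and −0.12) differed in sign; none of these 3 lists passed by camera or fry.

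The full treatment against antibody alone asked what Trim21 mRNA added to the antibody. Trim21 was higher by 3.79 ± 0.26 (adjusted p = 0.00040). Ribosome biogenesis genes were lower, 33 of 51 (38 adjusted over the list alone, median −1.44), with Nop14 at −3.06 (adjusted p = 0.00016) and Nop58 at −2.88 (adjusted p = 0.00027). So were 16 of 31 proteasome genes (21 adjusted over the list alone, median −1.12), with Psmc5 at −3.91. Of 23 NRF2 genes 12 fell and 1 rose (15 and 1 adjusted over the list alone, median −0.88), with the superoxide dismutase gene Sod1 at −3.94 ± 0.33 and the thioredoxin gene Txn1 at −2.44 ± 0.19. With an estimated correlation the adjusted p was 0.11 for these 3 lists, and the medians after quantile normalization were −0.89, −0.83 and −0.88. Of 10 COP9 subunits 3 were lower (4 adjusted over the list alone): Cops6 (−1.93, adjusted p = 0.00059), which kept its call under every scaling, Cops9 (−2.04, adjusted p = 0.0096; 0.075 without full-treatment replicate 2) and Cops4 (−0.77, adjusted p = 0.024). Cops4 was at −0.11 after quantile normalization (adjusted p = 0.63) and −0.10 after loess (0.73), and its call ended when any single array outside the antibody-alone group was left out (0.062 to 0.10). Cops3 was at 0.38 (adjusted p = 0.20) as deposited and was called higher after quantile normalization (0.92, adjusted p = 0.028) and loess (0.82, adjusted p = 0.047), as was Cops7a (0.52 as deposited, 1.22 and 1.19). The list had a median of −0.58 (−0.02 after quantile normalization; adjusted p = 0.10 by camera and 0.0031 by fry). Maternal genes went both ways, 14 higher and 12 lower of 59 (16 and 17 adjusted over the list alone). Their median of −0.20 (mean 0.03, adjusted p = 0.78) turned to 0.35 after quantile normalization (adjusted p = 0.00018) and 0.62 after loess (adjusted p = 1.4e-08). The oocyte genes Nobox (2.15 ± 0.21) and Npm2 (2.35 ± 0.25) were among the higher. The 2-cell list was at 0.73 (adjusted p = 0.16; 0.00038 after quantile normalization, 0.00034 after loess and 0.0020 without antibody-alone replicate 2), and the early lineage list, at 0.08 (−0.03 after median centring, mean −0.02), did not pass. The histone gene H3f4 (4.28 ± 0.30), Tmem181a (4.02 ± 0.26) and Trem1 (3.45 ± 0.23) were among the largest rises, and Tsn (−5.32 ± 0.25), Phlda2 (−4.93 ± 0.20) and Pdhb (−4.47 ± 0.21) among the largest falls.

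In all 1343 genes rose and 3217 fell, with 29.5% higher as deposited, 21.4% after median centring, 49.0% after quantile normalization and 47.3% after loess. Of 24 lists 14 were lower (adjusted p of 0.11 to 0.47 with an estimated correlation). Calls of DNA replication (adjusted p = 0.15), RNA polymerase II (0.10), cullin-RING (0.061), stress response (0.078), glycolysis (0.12) and p53 (0.56) genes ended without antibody-alone replicate 2, and the last also without full-treatment replicate 2 (0.13). These 6 calls ended after quantile normalization and loess as well. The mRNA decay genes, at −0.25 (0.07 after quantile normalization), were called without full-treatment replicate 1 (0.023) or antibody-alone replicate 1 (0.0027). The count of 4560 was 3005 without either non-manipulated array, 2490 without full-treatment replicate 2, 10443 and 8449 without antibody-alone replicate 1 or 2, 1408 with only these groups fitted and 2003 with a spread for each group.

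The full treatment against non-manipulated embryos combined injection, Trim21 mRNA and antibody. All 51 ribosome biogenesis genes fell (51 adjusted over the list alone, median −2.93), with the snoRNP proteins Nop58 at −3.95 and Fbl at −3.79, and 32 of 33 ribosomal protein genes (33 adjusted over the list alone, median −2.41). Of 59 maternal genes 25 rose and 3 fell (26 and 4 adjusted over the list alone, median 0.61), and of 22 transient 2-cell genes 12 rose and 3 fell (13 and 3 adjusted over the list alone, median 1.65). With an estimated correlation the adjusted p was 0.080, 0.082, 0.36 and 0.31, and the medians after quantile normalization were −1.99, −1.38, 1.32 and 2.61. Zscan4f (2.76, adjusted p = 0.00099), Oosp2 (2.68, adjusted p = 0.00014) and Rela (3.16 ± 0.20) rose. Tead4 (−3.60, adjusted p = 7.4e-05), Nedd8 (−3.58, adjusted p = 0.00016), Ssr2 (−6.20 ± 0.27) and Tsn (−5.72 ± 0.25) fell. Of 10 COP9 subunits 4 were lower as deposited (4 adjusted over the list alone), of which Cops6 (−2.79) kept its call under every scaling. Cops4 (−1.43) was at −0.42 after quantile normalization (adjusted p = 0.074), Cops9 (−1.36) at −0.87 (0.083) and Gps1 (−0.81) at 0.19 (0.46), and loess ended these 3 calls too. Those of Cops9 and Gps1 also ended without either non-manipulated array, either Trim21 mRNA array or full-treatment replicate 2 (adjusted p of 0.053 to 0.19). Cops3 was at −0.28 (adjusted p = 0.21), at −0.53 after median centring (adjusted p = 0.041) and at 0.60 after quantile normalization (adjusted p = 0.076), and Cops7b at −0.06 turned to 0.81 after quantile normalization (adjusted p = 0.017). Their median of −0.71 (adjusted p = 0.082 with an estimated correlation) turned to 0.31 after quantile normalization. Blood and immune markers passed as higher (2 of 13, 2 adjusted over the list alone, median 0.50, adjusted p = 0.039; adjusted p = 0.36 with an estimated correlation). That call by camera ended under each scaling (adjusted p = 0.053 after median centring, 0.52 after quantile normalization and 0.43 after loess) and without full-treatment replicate 2 (0.12) or non-manipulated replicate 2 (0.058). Sperm and oviduct markers (medians 0.30 and 0.39) were called by fry (adjusted p = 0.037 and 0.026) and not by camera (0.17 and 0.16). All genes at a mean log2 level of 4 to 6 had a median of 0.39 in this comparison.

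In all 4643 genes rose and 5097 fell, and 47.7% were higher as deposited, 25.6% after median centring, 49.4% after quantile normalization and 48.3% after loess. Rises were the majority without the antibody-alone group (59.9%), with a spread for each group (58.7%), with only these groups fitted (56%) and over all clusters (56.9%). Of 24 lists 20 were called, 17 lower and 3 higher, with an adjusted p of 0.080 to 0.36 with an estimated correlation. Calls of cullin-RING, stress response, p53, mRNA decay, glycolysis, COP9, early lineage and blood genes ended after quantile normalization and loess. Cumulus markers had a median of 0.13 (−0.18 after quantile normalization) and a mean of −0.28, and interferon genes, at 0.33 (−0.07 after quantile normalization), were called without full-treatment replicate 1 (adjusted p = 0.045). The count of 9740 was 3935 and 3975 without non-manipulated replicate 1 or 2, 5415 without full-treatment replicate 2, 17538 without either antibody-alone array, 14700 with only these groups fitted and 15733 with a spread for each group. In none of the 6 comparisons did a list pass camera's test with an estimated correlation. That test rests on 4 residual degrees of freedom. COP9 and NRF2 genes, with estimated correlations of −0.05 and 0.02, also lost their calls in the full treatment against Trim21 mRNA. A lost call therefore does not by itself show correlation between genes. The estimates themselves lay above the preset correlation for every tested list but COP9. They were 0.10 for proteasome, 0.13 for ribosome biogenesis, 0.20 for maternal, 0.25 for ribosomal protein and 0.28 for mitotic genes. If these estimates hold, camera's p at the preset correlation is too small for those lists.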

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

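All tests of explanations in this part were chosen after the results were seen.

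The antibody's change with Trim21 mRNA (full treatment against Trim21 mRNA) and without it (antibody alone against non-manipulated embryos) differed at 1253 genes by limma's interaction test, which is why the following values are listed. Each is the first change minus the second. List medians that differed were −1.51 for ribosomal proteins, −1.42 for ribosome biogenesis, −1.10 for the 26S proteasome, −0.79 for heat shock, −0.70 for splicing factors, −0.64 for oxidative phosphorylation, −0.62 for NRF2 genes, −0.48 for mitotic genes, −0.42 for RNA polymerase II and general transcription factors. Further medians were −0.37 for cullin-RING genes (0.10 after quantile normalization), −0.35 for DNA replication, −0.33 for the unfolded protein and integrated stress responses, 0.29 for maternal transcripts and 0.69 for transient 2-cell transcripts. None of these 14 lists passed with an estimated correlation. All genes had a median difference of −0.25 at a mean log2 level of 8 to 10, −0.42 at 10 to 12 and −0.71 at 12 to 14. Several of the listed medians were no larger, and no level-matched lists were drawn for the interaction. Genes with a positive difference were Tmem181a (3.62), H3f4 (3.58), Trem1 (3.37), Spry4 (3.31), Rela (2.78), E2f2 (2.72), Oog4 (2.56), Gatd3a (2.35), Pak4 (2.35) and Maea (2.24). Genes with a negative difference were Phlda2 (−5.71), Tsn (−4.36), Calcoco2 (−4.25), Actr6 (−4.18), Dcaf13 (−4.10), Rab24 (−4.06), Dppa5a (−3.95), Trim43b (−3.84), Pdhb (−3.77) and Selenos (−3.77). Of these 20 genes 8 kept their call without non-manipulated replicate 1, 6 without replicate 2, 12 without either Trim21 mRNA array, 17 and 16 without full-treatment replicate 1 or 2, and 20 without either antibody-alone array.

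Transcript clusters that name no gene or several lay outside the gene comparisons. Of 34698, 3644 changed in the full treatment against Trim21 mRNA (1936 higher, 1708 lower), against 0 for Trim21 mRNA against non-manipulated embryos in limma's fit of all clusters. What these clusters transcribe, and how many change under another scaling or beside clusters of like level, was not examined.

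Genes of ribosomes and RNA processing were lower and maternal transcripts higher in both antibody groups. Compression of the signal on the full-treatment arrays is argued against as the whole cause by quantile normalization, which gives all arrays 1 distribution. It left the ribosome biogenesis median at −1.98, where 95% of 10000 random lists of the same size and levels lay between −0.70 and 0.64. The maternal median was then 1.88 (−0.63 to 0.52). With antibody alone these medians were −0.91 (−0.39 to 0.28) and 0.94 (−0.33 to 0.24). The random lists lack the correlation between genes of these 2 lists, estimated at 0.13 and 0.20. Their ranges are therefore too narrow to serve as a test, and they describe how far level alone moved such lists. A failure to begin the transcription of the 2-cell stage is argued against in the full treatment by the transient 2-cell list, which was higher by 1.77, and stays open with antibody alone, where the list was at 0.67 (0.23 and 1.19 on its arrays) and its call ended without replicate 2 (adjusted p = 0.42). Embryos that lagged or stayed undivided and so kept maternal transcripts stay open as an explanation: the maternal median of 0.72 with antibody alone (0.44 and 0.78 on its arrays; the call ended without replicate 2, adjusted p = 0.17) is part of the pattern, and a direct action of the antibody could give it too. Day of treatment and antibody cannot be told apart, because every group had its own day; the groups without antibody, also on separate days, differed in the ribosome biogenesis median by −0.14 and in the maternal median by −0.27.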

How the results depend on the processing

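Of the results of named genes under the alternatives, 7810 kept their side of the threshold, 934 fell below it and 11 passed it. Another 3 changed direction with a call in the main test or the alternative. Of the list results 1985, 287, 27 and 5 did. A change of direction without a call in either is counted among those that kept their side. Chosen after seeing the data were the spread for each group, the fits without the antibody-alone group or the genes at a ceiling, the list tests after quantile normalization and loess, the level-matched random lists, and all alternatives of the genes called the same way in both antibody comparisons. Causes below were not tested, unless the setting's own construction gives them.

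Quantile normalization turned Cops3 in the full treatment against Trim21 mRNA to 0.03 and Gps1 in the full treatment against non-manipulated embryos to 0.19 (0.11 after loess). Trim21 mRNA against non-manipulated embryos held 0 genes after quantile normalization, median centring or loess, with a trended robust prior and over all transcript clusters (1 in the main test, 1928 at an unadjusted p under 0.05). In the order full treatment against Trim21 mRNA, antibody alone against non-manipulated, Trim21 mRNA against non-manipulated, full treatment against antibody alone and full treatment against non-manipulated, the gene counts were 10891, 0, 2520, 1408 and 14700 with only the groups compared in the fit, which leaves the spread of those groups alone. They were 11944, 1177, 3739, 2003 and 15733 with a spread for each group. Without the antibody-alone group the first was 14192 and the last 17538; the pools of that group varied most. The last was 15721 over all transcript clusters, which are more features, and 6062 with an added 2-fold threshold, which can only lower it.

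No list passed with an estimated correlation: the number was 0 in all 6 comparisons. That form of the test has 4 residual degrees of freedom and little power, so the number does not show correlation between genes. The estimated correlations themselves lay above the preset for every tested list but COP9. If they hold, camera's p at the preset is too small for those lists. In the same order fry called 21, 16, 0, 16 and 23 lists, and 6 for the interaction, where camera called 18, 17, 15, 14 and 20, and 14. In that order of comparisons, camera called 11, 9 and 6 lists for the first 3 and 13 for the last among genes above the median of mean level. After loess it called 11, 10 and 9 for the first 3, 12 for the last and 9 for the interaction, and after quantile normalization 11, 10, 7, 12 and 9. The test of mRNA decay genes in the full treatment against Trim21 mRNA turned from lower to higher after loess (adjusted p = 0.96) and quantile normalization (adjusted p = 1). So did that of maternal genes in the full treatment against antibody alone after loess (1.4e-08) and quantile normalization (0.00018), and that of COP9 subunits in the full treatment against non-manipulated embryos after quantile normalization (0.89). The correlation of the antibody's changes with and without Trim21 mRNA was 0.619 after loess, against 0.684. Genes lower in both were 1917 and became 1099 after quantile normalization; genes higher in both were 389 and became 826 after quantile normalization, 226 after median centring and 916 after loess. Both were 0 with only the groups compared in the fit.

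With each array left out in turn the gene counts ran from 3366 to 14192 for the full treatment against Trim21 mRNA, 94 to 13792 for antibody alone against non-manipulated, and 0 to 1 for Trim21 mRNA against non-manipulated. They ran from 2490 to 10443 for the full treatment against antibody alone, 3935 to 17538 for the full treatment against non-manipulated and 99 to 5663 for the interaction. The highest counts came without an antibody-alone array; the array left in that group then adds nothing to the estimated spread. Lists called ran from 9 to 15 for the full treatment against antibody alone and from 6 to 14 for the interaction, and the correlation from 0.599 to 0.688. Genes lower in both antibody comparisons ran from 69 to 3943 and genes higher in both from 11 to 3795.

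With the replicate number as a block Trim21 mRNA against non-manipulated embryos held 0 genes; pairing by number has no basis in the arrays, since the deviations of equal numbers correlated between −0.191 and 0.143 across genes.

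On the full-treatment arrays and antibody-alone replicate 1 the ceiling limits what high levels can show, and 12 genes lay at it. The number of pools limits all comparisons, and the simulated 2-fold changes were mostly missed (29.9% recovered for the full treatment against Trim21 mRNA). The simulation changed 200 genes, where 7125 were called in that comparison, so its adjustment of p was stricter. The recovered share therefore does not give that of the data. In the simulated comparisons that involve the antibody-alone group, false calls were a larger share of called genes than the threshold allows. Calls in those comparisons may therefore hold more false ones than the threshold states.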

Other observations

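All results and tests in this part were chosen after the values were seen.

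Small nucleolar RNAs, which guide the modification of ribosomal RNA, were mostly higher in the full treatment against Trim21 mRNA, where the mRNAs of ribosome biogenesis were lower (median −2.80). With antibody alone against non-manipulated embryos both were lower (−1.20 for ribosome biogenesis). Of 70 with a mean log2 level above 8, 46 rose and 3 fell in the full treatment against Trim21 mRNA (median 1.72), while 2 rose and 21 fell with antibody alone against non-manipulated embryos (median −0.79). The mean was taken over all arrays, so small nucleolar RNAs that were high in the full treatment entered more easily. Their median level on the arrays was 9.59 and 9.39 in non-manipulated embryos, 10.14 and 10.56 with Trim21 mRNA, 11.66 and 12.00 in the full treatment and 7.93 and 8.72 with antibody alone. The interaction was 2.59 in the median, with 24 higher and 0 lower by limma, and both directions held under the 3 scalings (medians of 1.51 to 2.59 and of −0.92 to −0.45). Trim21 mRNA against non-manipulated embryos had a median of 0.64 with 0 called. The 207 small nuclear RNAs had a median of 0.28 in the full treatment against Trim21 mRNA (19 higher, 2 lower), which was 0.07 after median centring, 1.12 after quantile normalization (45 higher) and 0.97 after loess (41 higher). With antibody alone it was −0.08, which turned to 0.21 after quantile normalization (0 higher and 13 lower as deposited), and for Trim21 mRNA against non-manipulated embryos 0.59, with 204 members above 0 and 0 called. The median level of small nuclear RNAs was 9.80 and 8.44 on the antibody-alone arrays, against 9.24 and 9.23 in non-manipulated embryos. The antibody-alone pools thus went opposite ways.

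Y RNAs, short RNAs of the Ro ribonucleoprotein, were low with antibody alone: Rny1 stood at 9.20 and 8.17 there, against 11.83 and 11.60 in non-manipulated embryos (−3.03, adjusted p = 0.0060). Rny3 stood at 9.35 and 11.68 against 16.10 and 16.16 (−5.62, adjusted p = 0.0059). In the full treatment Rny1 stood at 15.95 and 16.21, higher than with Trim21 mRNA by 2.17 (adjusted p = 0.0053), and Rny3 at 18.04 and 17.81 (0.30, adjusted p = 0.75). Without antibody these RNAs already differed between the groups, which lay on separate days, by 2.20 for Rny1 (adjusted p = 0.44) and 1.49 for Rny3 (adjusted p = 0.82) with Trim21 mRNA against non-manipulated embryos. The interaction was 5.20 for Rny1 (adjusted p = 0.0052) and 5.92 for Rny3 (adjusted p = 0.020). Terc, the telomerase RNA, was lower with antibody alone (−1.32, adjusted p = 0.016) and in the full treatment against Trim21 mRNA (−1.42, adjusted p = 0.0041). Of the other RNAs looked at, Rpph1, the RNase P RNA, passed in neither comparison (−0.91, adjusted p = 0.26, and 1.30, adjusted p = 0.10) nor in the interaction (2.20, adjusted p = 0.17). By limma Rpph1 was higher in the full treatment against antibody alone (3.15, adjusted p = 0.0066) and against non-manipulated embryos (2.24, adjusted p = 0.015). Rn7sk passed in neither antibody comparison (−0.12, adjusted p = 0.58, and −0.42, adjusted p = 0.084), but lay at the ceiling of the full-treatment arrays and within 0.01 of that of antibody-alone replicate 1, where a change cannot be read.

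Quantile normalization could not decide whether compression of the signal caused the rise of small nucleolar RNAs in the full treatment. Compression lowers high levels, and all genes at a mean log2 level of 8 to 10 had a median of −0.60 there. Undoing it would enlarge a rise at these levels. The median of small nucleolar RNAs was 1.72 as deposited and 2.59 after quantile normalization. Their choice by mean level over all arrays also favours such a rise. With antibody alone the median was −0.45 after quantile normalization. A shared action of the antibody stays open, although the median was −0.79 without Trim21 mRNA and positive with it, since a difference between days could turn either sign. Recovery of small RNA that differed by day cannot be told apart from the groups: the median already differed by 0.64 between the groups without antibody, which lay on separate days. No biological explanation was tested.

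The antibody-alone pools differed by more than 2-fold at 4616 genes, 2124 higher in replicate 1 and 2492 in replicate 2. An array of a Trim21 mRNA group under a wrong label is argued against, since the higher of the Trim21 levels of these arrays was 6.76. Compression on replicate 1 is argued against as the whole cause, since 4309 genes still differed after quantile normalization. Unequal shares of affected embryos in the pools could also separate them, and stay open. Across genes, which are not independent replicates, the difference of replicate 1 from replicate 2 correlated with the full treatment's change at 0.238 (0.105 after quantile normalization), and the difference of each from non-manipulated embryos at 0.599 and 0.623. Levels of replicate 2 correlated with the non-manipulated arrays at 0.9748 and 0.9759, and differed from them 2-fold at 3300 and 3090 genes. Replicate 2 thus lay nearer to them than to replicate 1 (0.9558, 4616 genes). Replicate 1 differed from the non-manipulated arrays 2-fold at 6608 and 6509 genes. Embryos were not scored per pool in the sources used here.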
